A study of Mus musculus with 12 samples.

How the data were processed

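The 12 libraries come from B16F10 mouse melanoma cells after 6 h with vehicle, Poly(I:C), QS-21 or both, 3 libraries per group. Sample titles give a letter and a number. The letters V, P and Q were read as the initials of vehicle, Poly(I:C) and QS-21 in the series' design text, and the remaining letter as the combination, since it is the one condition left. Doses and the vehicle are not given in the sources used here, nor whether the libraries of a group came from separate cultures. Per the labels' protocols, RNA was selected with poly-T beads, made into libraries with a kit that does not mark the strand, and sequenced in paired ends on an Illumina instrument.

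The deposited table holds a whole-number count and an FPKM value per gene and library. Per the submitters' processing notes the authors used fastp, HISAT, StringTie, Cufflinks, featureCounts and DESeq2, with no versions and no role for each tool, and the genome build is not given in the sources used here. The deposited counts were used as they stand. The FPKM values, also made by the authors, were used for 1 check only. Relative to vehicle 1, the library total each FPKM column implies matched the ratio of summed counts to within 2.7e-06 percent. A factor common to all columns was not tested. Counts of 1 to 9 were even in 65.7% to 71.1% of cases per library, a pattern that arises when both reads of a pair are counted, in which case the error of a low count is larger than its size implies. Of 23258 genes 22240 were matched by identifier to a GENCODE annotation of GRCm38. All lay on the same chromosome there, but 443 had the same start and end, so positions are given as the table has them and none were taken from that annotation. There were 0 rows without a gene name. Genes that share reads with close relatives, such as the Gbp, Ifit and H2 families, and genes that overlap on opposite strands are uncertain, since how shared reads were counted is not given.

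Choices of groups, tests, gene lists and alternatives were made before the data were examined, unless stated otherwise. Counts were analysed with edgeR 4.0.16 in R 4.3.3, with TMM factors (0.979 to 1.02), filterByExpr by group, which left 13850 genes, and 1 quasi-likelihood fit with a mean per group over all 12 libraries. Each treatment was tested against vehicle, the combination against each single treatment, and the interaction as the combination minus both single treatments plus vehicle on the log2 scale. P-values are 2-sided, Benjamini-Hochberg adjusted per comparison, with a threshold of 0.05 and no fold minimum. Genes past both single treatments have the same sign in both tests, and the larger p of the pair was adjusted. CPM values are normalised by TMM and given as mean ± SD over 3 libraries. A comparison of Poly(I:C) with QS-21 was added after the data had been seen.

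Of 32 gene lists written in advance, 28 had at least 5 tested members and were tested with camera (limma 3.58.1), with a preset inter-gene correlation of 0.01 and again with an estimated one. Of 706 list entries 672 were found in the table. Lists of interferon genes, MHC class II genes, leukocyte markers and epithelial markers had too few tested members. Genes are named by rule: per comparison the 5 largest rises and 5 largest falls with a mean of at least 2 log2 CPM in the higher group and no overlap between libraries (chance gives no overlap for 10% of unchanged genes with 3 against 3), and the 3 members with the smallest p in each described list. For the interaction no filter on overlap was applied, and the mean was that of the group with the highest mean. In addition Ifnb1, Cxcl10, Isg15 and Ifit1 were among the genes fixed for every comparison. Some genes that the rule names are not reported here.

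Total counts were 42.53, 33.95 and 34.5 M in vehicle, 37.11, 36.14 and 33.77 M in Poly(I:C), 36.75, 35.53 and 35.44 M in QS-21 and 43.75, 36.23 and 41.15 M in the combination libraries. The median standard error of a log2 change was 0.094 for each single treatment against vehicle and 0.132 for the interaction. A count of 0 was taken to allow up to 3 counts. This floor covers counting error only, and it is too low if both reads of a pair were counted. The 10 genes with the most counts took 7.07% to 7.72% of a library. No 2 libraries of a group were alike within sampling noise (chi-square per degree of freedom 6.63 to 24.29).

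The fit was tested on simulated counts for 13635 genes in which only the combination was changed. Of genes with a mean above 1 CPM, 100 were changed by 1.5-fold and 100 by 2-fold, so recovery at lower counts was not tested. The fit recovered 87 and 97 of them for combination against vehicle, 88 and 94 against Poly(I:C) and 85 and 94 against QS-21. It recovered 68 and 85 for the interaction and 83 and 92 for genes past both. Among 13435 unchanged genes there were 10, 15, 11, 11 and 2 calls in the same order.

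Alternatives planned in advance were RLE factors, no filter, a minimum of 1 CPM in 3 libraries, DESeq2 1.42.0, fits of only the groups compared, the replicate number as a block, an estimated inter-gene correlation and leaving out each library. Those chosen after seeing the data were vehicle 3 as the only vehicle library, leaving out the 4 libraries with intestinal transcripts, and an enrichment test of KEGG terms with 10 to 300 genes. Markers of 6 other tissues were listed after some heart and intestinal genes had been noticed, but before the lists were counted. Of each list, markers with at least 10 counts and a mean under 1 CPM were used. Of 32 listed heart markers 11, and of 32 intestinal markers 4, were at 1 CPM or more in these cells and so were not used. No marker stood in 2 of the tissue lists. Markers with a higher mean CPM, here scaled to total counts only, in the single-treatment libraries than in the others were counted. They were 18 of 19 for heart muscle, 2 of 26 for intestinal epithelium and 5 of 9 for skeletal muscle. For liver they were 3 of 5, for brain 2 of 4 and for blood 1 of 7.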

Results

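Polyadenylated RNA from B16F10 cells, a pigmented mouse melanoma line, was sequenced after 6 h of treatment in culture. The 4 groups of 3 libraries had received vehicle, Poly(I:C), QS-21, or both together. Poly(I:C) is a synthetic double-stranded RNA that stands in for viral RNA at TLR3 and RIG-I-like receptors. QS-21 is a saponin from the soap bark tree, used as a vaccine adjuvant, that binds cholesterol in membranes. The deposited table gives counts for 23258 genes, of which 17477 are protein-coding, and total counts ran from 33.77 to 43.75 M per library (M for mega). After the filter on low counts 13850 genes were tested. No label says that the 3 libraries of a group came from separate cultures, so the p-values measure the spread between libraries, which may be technical.

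Gene-wise variation between libraries of a group was small, with a median biological coefficient of variation of 7.7%. Of 2173 abundant genes, 4 ranged over more than 1 log2 unit within a group: Gapdh, a glycolysis enzyme, the ribosomal protein genes Rps27a and Rpl17, and the mitochondrially encoded mt-Co2. Gapdh stood at 77.9, 603 and 83.7 CPM in the 3 vehicle libraries and Rps27a at 1081, 639 and 407 CPM. The libraries also differed in transcripts that do not follow the labels alone. Myh6, the cardiac myosin heavy chain, had 479 counts over the 6 libraries treated with a single agent and 9 over the 6 vehicle and combination libraries. The genes named in this paragraph were chosen after their values had been seen. The Myh6 count was 33 to 146 in each of the former and at most 3 in each of the latter. Of 19 low-count heart muscle genes, 18 had more counts in the single-treatment libraries. A second set of transcripts, from genes of intestinal epithelium such as Muc2, Muc3 and Lypd8, was found in 4 libraries. The summed counts of 26 such genes were 555 in vehicle 1, 519 in vehicle 2, 150 in Poly(I:C) 2 and 308 in Poly(I:C) 3, against 27 to 55 in the other 8 libraries. Vehicle 1 and vehicle 2 also had a count for 18454 and 18462 genes, against 16525 to 17053 in the other 10. Only combination against vehicle and Poly(I:C) against QS-21 compare groups that are alike in Myh6.

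**Figure D1:**
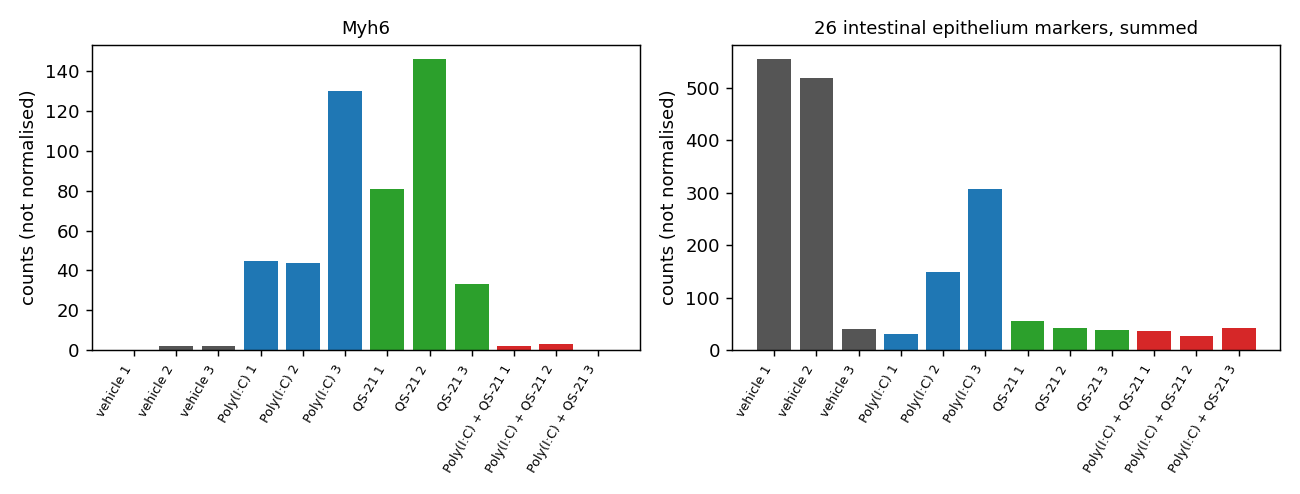
Counts, not normalised, of Myh6 (left) and of 26 intestinal epithelium genes summed (right) in each of the 12 libraries, with bars coloured by group. Myh6 reached 33 to 146 counts in the 6 single-treatment libraries and at most 3 elsewhere, and the intestinal genes stood out in vehicle 1 and 2 and Poly(I:C) 2 and 3.

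Poly(I:C) alone was compared with vehicle to ask what the double-stranded RNA mimic does by itself. Interferon-stimulated genes, the antiviral programme that follows type I interferon signalling, rose together. Of the 53 tested, 46 were higher (49 adjusted over the list alone), with a median log2 fold change of 1.39. Usp18, which restrains interferon receptor signalling, rose from 2.02 ± 0.38 to 17.4 ± 2.6 CPM (counts normalised to library size; mean ± SD, n = 3), and Rigi, a cytosolic sensor of viral RNA, rose 4.21-fold. Interferon-inducible GTPases, which act against intracellular pathogens, rose in 11 of 13 cases (12 adjusted over the list alone), with a median of 2.24 and with Igtp at 8.13-fold. Among cytokines and chemokines 8 of 16 were higher (9 adjusted over the list alone), among them Cxcl10, a T cell attractant, from 11.1 ± 0.81 to 67.5 ± 6.3 CPM, and Ccl5 at 2.60-fold.

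Genes of cholesterol synthesis and uptake also rose. Of 25 tested, 22 were higher after Poly(I:C) (24 adjusted over the list alone), with a median log2 fold change of 1.15. Insig1, which retains SREBP transcription factors in the endoplasmic reticulum, rose 4.19-fold, from 41.3 ± 1.3 to 173 ± 0.48 CPM, and the sterol synthesis enzymes Msmo1 and Cyp51 rose 4.25-fold and 3.02-fold. Fatty acid synthesis genes were higher in 8 of 12 cases (8 adjusted over the list alone), with Elovl6 at 2.01-fold and Fads2 at 1.58-fold.

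The unfolded protein and integrated stress response fell in 17 of 24 genes (20 adjusted over the list alone; median −0.30). Chac1 and Trib3, both induced by the transcription factors ATF4 and CHOP under stress, were at 0.362 and 0.439 of their vehicle level, and Herpud1, of endoplasmic reticulum quality control, was at 0.526. Pigment cell genes were lower in 13 of 21 cases (15 adjusted over the list alone; median −0.21), with Trpm1 at 0.661, and lysosomal genes in 11 of 31, with 1 higher (15 and 1 adjusted over the list alone) and the sialidase Neu1 at 0.709. The largest falls also included Slc25a34, a mitochondrial carrier, at 0.289, and Nupr1, a stress-induced chromatin factor, at 0.420. The calls of Neu1 (log2 −0.30) and Nupr1 (−0.70) ended without the 4 libraries with intestinal transcripts.

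In all, 684 genes were higher and 619 lower after Poly(I:C) (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted), 109 and 42 of them by over 2-fold. Adjusted p was 3.50e-13 for Cxcl10, 5.79e-10 for Ifit1, 9.94e-10 for Isg15, 1.30e-14 for Insig1 and 1.09e-07 for Chac1 in this test. Of 28 gene lists, 17 passed camera with its preset correlation and 12 with an estimated one. The latter kept interferon-stimulated genes (adjusted p = 0.000111), GTPases (0.000502), cholesterol genes (1.74e-06), the stress response list (0.000111), cytokines (0.0037), fatty acid synthesis (0.00469), pigment genes (0.00315) and lysosome (0.00959). MHC class I genes, with 8 of 21 higher and 1 lower (12 and 2 adjusted over the list alone), passed only with the preset value (adjusted p = 2.20e-05, and 0.0759 with an estimated correlation). The 684 and 619 became 454 and 398 without vehicle 2, the latter also 377 without Poly(I:C) 2, 226 and 264 without the 4 libraries with intestinal transcripts, and 218 and 197 with vehicle 3 as the only vehicle library. Poly(I:C) libraries had 44 to 130 Myh6 counts and vehicle libraries at most 2, and 5 of 20 tested heart genes were among the higher calls.

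QS-21 alone was compared with vehicle to ask what the saponin does by itself. The cholesterol list had the smallest camera p, with 22 of 25 genes higher (23 adjusted over the list alone) and a median log2 fold change of 1.09. Idi1, an isoprenoid isomerase, rose 4.75-fold, Insig1 4.17-fold to 173 ± 1.2 CPM and Msmo1 3.92-fold to 177 ± 8.4 CPM. Fatty acid synthesis genes were higher in 8 of 12 cases (8 adjusted over the list alone), with Scd2 at 1.62-fold.

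The stress response list fell in 19 of 24 genes (19 adjusted over the list alone; median −0.32), with Chac1 at 0.290, Trib3 at 0.366 and Herpud1 at 0.549 of vehicle. Slc7a11, the cystine carrier that feeds glutathione synthesis, was at 0.363. Pigment cell genes were lower in 10 of 21 cases (14 adjusted over the list alone) and lysosomal genes in 11 of 31, with 1 higher (14 and 1 adjusted over the list alone). Cell cycle genes were higher in 11 of 34 cases and lower in 1 (17 and 1 adjusted over the list alone), with Ccnd1, the G1 cyclin, at 1.45-fold and Rrm2, a ribonucleotide reductase subunit, at 1.26-fold, while Cdk2 was at 0.800. After Poly(I:C) 8 of this list were higher and 1 lower (12 and 1 adjusted over the list alone, camera adjusted p = 0.0224 with an estimated correlation). Between the 2 agents 0 were called higher and 0 lower (0 and 1 adjusted over the list alone). The list was lower after Poly(I:C) than after QS-21 by camera with the preset correlation (adjusted p = 0.000556, median −0.03). It did not pass with an estimated correlation (adjusted p = 0.0591).

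The interferon-stimulated genes were close to vehicle after QS-21. Ifit1 was the one called of 53 (1 adjusted over the list alone), at 1.41-fold, and the median log2 change was 0.04. Cxcl10 was at 15.8 ± 0.14 CPM, a 1.42-fold rise, and Isg15 at 6.92 ± 0.50 against 7.04 ± 1.2 CPM in vehicle. Ifnb1, the interferon beta gene, had 0 counts in each of the 9 vehicle and single-treatment libraries. This allows up to 3 counts per library, or more if both reads of a pair were counted. It had 4, 0 and 2 counts in the combination libraries, too few to test at this depth.

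After QS-21, 585 genes were higher and 540 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted), 45 and 42 of them by over 2-fold. Adjusted p in this test was 1.35e-14 for Insig1, 2.25e-08 for Chac1, 0.000548 for Cxcl10, 0.0112 for Ifit1 and 0.93 for Isg15. Of 28 lists 15 passed camera, and 9 with an estimated correlation, among them cholesterol genes (adjusted p = 1.39e-06), the stress response (7.26e-05), fatty acid synthesis (0.00629), cell cycle (0.00629), pigment genes (0.00821) and lysosome (0.0188). For interferon-stimulated genes adjusted p was 0.0485 with the preset and 0.436 with an estimated correlation. Leaving out 1 library changed the 585 and 540 to 322 and 356 (vehicle 1), 322 and 338 (vehicle 2), 326 and 315 (QS-21 1) or 349 and 344 (QS-21 3), and they were 130 and 175 without the 4 libraries with intestinal transcripts and 103 and 137 with vehicle 3 as the only vehicle library. The Ifit1 call ended without vehicle 1 (log2 0.47) or QS-21 3 (0.37). QS-21 libraries had 33 to 146 Myh6 counts and vehicle libraries at most 2, with 3 of 20 tested heart genes among the higher calls, and 4 of 14 tested intestinal genes were among the lower calls.

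The 2 single treatments were set against each other directly in a comparison added after the data had been seen. Poly(I:C) was higher in 42 of 53 interferon-stimulated genes (49 adjusted over the list alone; median log2 1.38) and in 8 of 13 GTPases (12 adjusted over the list alone; median 2.22). For cholesterol genes the median difference was 0.01 (camera, adjusted p = 0.557). Over all genes 89 were higher and 0 lower (edgeR quasi-likelihood, adjusted); at an unadjusted p under 0.05 there were 373 and 214, and DESeq2 called 114 and 2. The log2 changes of Poly(I:C) and QS-21 against vehicle correlated across genes at r = 0.614 (genes are not independent replicates), but both used the same 3 vehicle libraries. Simulated groups without any effect, set against a shared simulated vehicle group, gave a mean r of 0.493. Each gene was simulated on its own, so deviations that many genes share in the real vehicle libraries were not included. The covariance was 0.0949 against a simulated 0.02138, with 426 genes higher in both against 28.9 for independent lists and 428 lower in both against 24.1. In each of 20 simulations without any effect edgeR called 0 genes higher in both and 0 lower in both (adjusted; other thresholds and tools were not simulated). The 3 vehicle libraries do not split into groups of at least 2, so part of this excess may come from the shared controls. Both comparisons also cross the split by Myh6 counts in the same direction, with 33 to 146 in each single-treatment library and at most 2 in each vehicle library, and the simulations did not include that split.

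**Figure D2:**
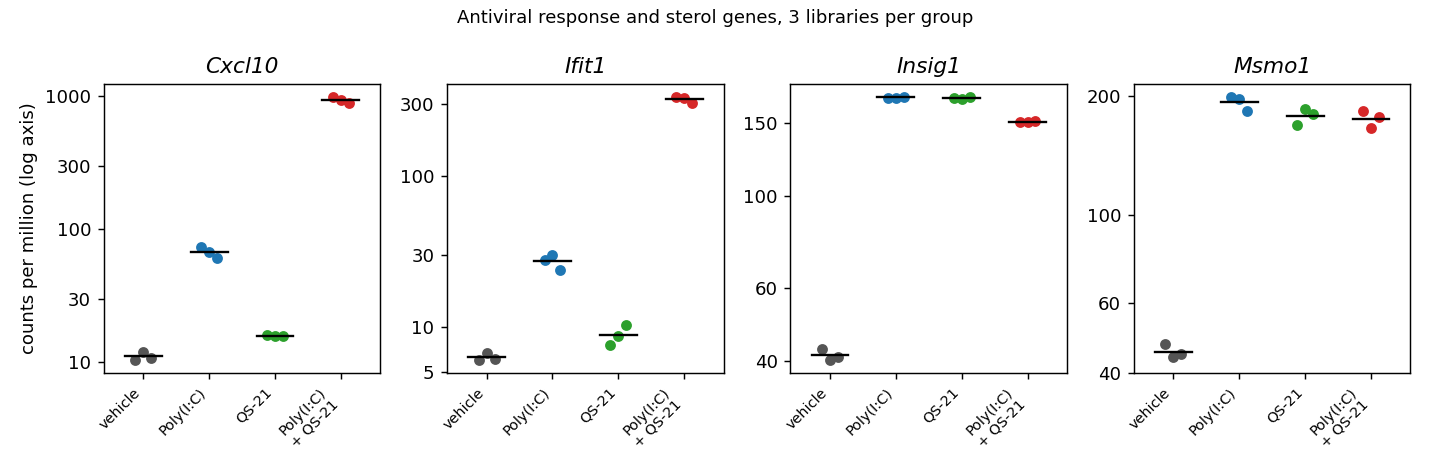
TMM-normalised CPM on a log axis for Cxcl10, Ifit1, Insig1 and Msmo1, one point per library and a bar at the mean of the 3 libraries of each group. Cxcl10 and Ifit1 reach 938 and 325 CPM in the combination, while Insig1 and Msmo1 lie at 151 to 173 and 175 to 192 CPM in every treated group, above 41.3 and 45.3 CPM in vehicle.

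Both agents together were compared with vehicle to ask what the combination does. Interferon-stimulated genes were higher in 52 of 53 cases (52 adjusted over the list alone), with a median log2 fold change of 3.85. Cxcl10 rose 84.7-fold to 938 ± 54 CPM, Usp18 64.4-fold to 130 ± 7.3 CPM, Ifit1, which binds viral RNA that lacks the host cap, 51.8-fold to 325 ± 17 CPM, and Isg15, a ubiquitin-like modifier, 31.0-fold to 220 ± 21 CPM. GTPases were higher in 12 of 13 cases (13 adjusted over the list alone; median 4.89), with Irgm1 at 10.1-fold and Gbp2 at 12.5-fold. Tgtp2 and Gbp6 of this list, and the nucleic acid sensor Zbp1, had almost no counts in vehicle, at 0.0357 ± 0.031, 0.0753 ± 0.080 and 0.122 ± 0.067 CPM, and reached 8.18 ± 0.91, 6.02 ± 0.29 and 8.06 ± 0.42 CPM.

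MHC class I antigen presentation genes were higher in 18 of 21 cases and lower in 2 (18 and 2 adjusted over the list alone; median 1.28). H2-K1, a class I heavy chain, rose 7.13-fold, the peptide-loading chaperone Tapbp 6.36-fold and the peptide transporter Tap1 4.39-fold. NF-kB target genes were higher in 16 of 19 cases (17 adjusted over the list alone; median 0.68), with Relb at 8.06-fold, Irf1 at 4.73-fold and Nfkb2 at 3.83-fold. Cytokines and chemokines were higher in 12 of 16 (13 adjusted over the list alone), with Ccl5 at 17.0-fold and Csf1, a macrophage growth factor, at 5.72-fold. p53 targets were higher in 10 of 21 (12 adjusted over the list alone), with the cell cycle inhibitor Cdkn1a at 2.12-fold. Of apoptosis genes 5 of 23 were higher (7 adjusted over the list alone): the pro-apoptotic Bid at 1.94-fold and Bbc3 at 1.85-fold were among them.

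Cholesterol genes were higher than in vehicle in 21 of 25 cases (23 adjusted over the list alone; median 1.04), with Insig1 at 3.66-fold and Msmo1 at 3.86-fold. The stress response list was lower in 11 genes and higher in 3 (12 and 3 adjusted over the list alone), with Herpud1 at 0.687 and Trib3 at 0.606 of vehicle while Atf3, a stress-induced transcription factor, rose 1.74-fold. Pigment cell genes were lower in 11 of 21 and higher in 1 (13 and 3 adjusted over the list alone). Slc25a34 was at 0.303 of vehicle. Snhg7os, named as an opposite-strand transcript of Snhg7, was at 0.309; reads of overlapping transcripts on opposite strands cannot be told apart in these counts.

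**Figure D3:**
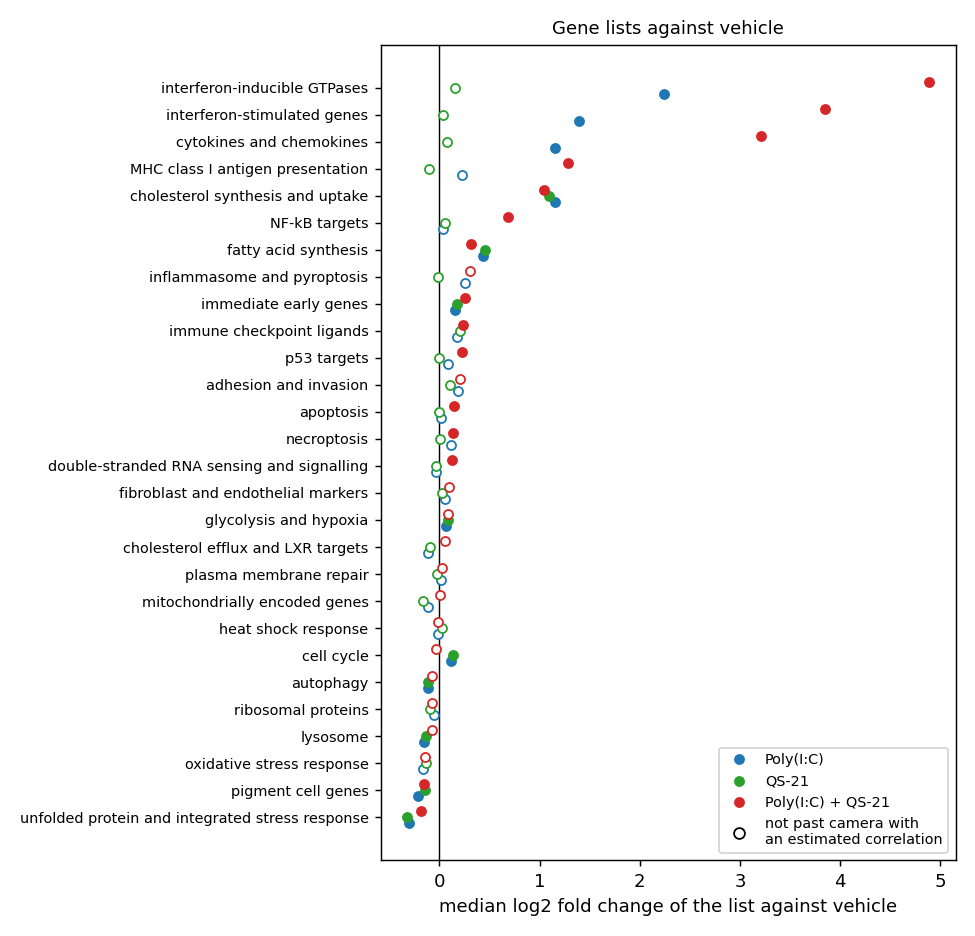
Median log2 fold change against vehicle of each of 28 gene lists after Poly(I:C), QS-21 and both, with filled points for lists past camera with an estimated correlation. Interferon-stimulated genes stand at 1.39, 0.04 and 3.85, and cholesterol genes at 1.15, 1.09 and 1.04.

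In the combination 1058 genes were higher and 741 lower than in vehicle (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted), 253 and 53 of them by over 2-fold. Adjusted p in this test was 3.25e-18 for Cxcl10, 6.14e-16 for Ifit1, 1.82e-14 for Isg15 and 5.43e-15 for Insig1. Of 28 lists 19 passed camera, and 15 with an estimated correlation, among them interferon-stimulated genes (adjusted p = 2.69e-05), GTPases (0.000163), MHC class I (0.00256), NF-kB targets (0.00131), cytokines (0.0007), cholesterol genes (7.17e-06), p53 targets (0.0048), apoptosis (0.0048), the stress response (0.0048) and pigment genes (0.016). The counts were 465 and 256 with vehicle 3 as the only vehicle library, and 498 and 267 without the 4 libraries with intestinal transcripts; of 14 tested intestinal genes 9 were among the lower calls here.

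The combination was set against Poly(I:C) alone to ask what QS-21 adds. Interferon-stimulated genes were higher in 51 of 53 cases (52 adjusted over the list alone), with a median log2 fold change of 2.05. Cxcl10 was 13.9-fold, Ifit1 12.0-fold, Oasl1, of the oligoadenylate synthetase family, 12.2-fold and Isg15 5.61-fold above Poly(I:C) alone. Slfn2, a lymphocyte quiescence gene with almost no counts in the other groups, rose from 0.255 ± 0.17 to 4.09 ± 0.83 CPM. MHC class I genes were higher in 17 of 21 (18 adjusted over the list alone), including B2m, the light chain, at 1.93-fold, and NF-kB targets in 16 of 19 (16 adjusted over the list alone), including Nfkbie at 4.64-fold. The checkpoint ligand Cd274, also known as PD-L1, stood at 5.78 ± 0.63, 5.27 ± 0.76 and 5.29 ± 0.72 CPM in vehicle, Poly(I:C) and QS-21 and at 14.6 ± 0.85 CPM in the combination.

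Against QS-21 alone, which asks what Poly(I:C) adds, 52 of 53 interferon-stimulated genes were higher (52 adjusted over the list alone; median 3.58), with Cxcl10 at 59.5-fold and Usp18 at 55.9-fold. The guanosine triphosphatase Iigp1 went from 0.0745 ± 0.087 to 9.07 ± 0.53 CPM. Of the stress response list 11 of 24 were higher (13 adjusted over the list alone), with Atf3 at 3.21-fold and Chac1 at 1.99-fold; against Poly(I:C) they were 10 of 24 (12 adjusted over the list alone). Cell cycle genes were lower than after QS-21 in 15 of 34 cases (22 adjusted over the list alone), with the replication licensing factor Cdc6 at 0.759 and Rrm2 at 0.798, and lower than after Poly(I:C) in 5 of 34 (13 adjusted over the list alone). Rrm2 stood at 373 ± 3.9 CPM in the combination and 372 ± 4.5 CPM in vehicle, against 440 ± 15 and 468 ± 7.2 CPM after the single agents. Against vehicle 1 of 34 cell cycle genes was higher and 2 were lower in the combination (median −0.03). This pattern follows the split of the libraries by Myh6 counts, so a handling difference cannot be told apart from an effect of the agents. Polr3g, an RNA polymerase III subunit, was at 0.670 and 0.600 of the single treatments, the former call ending without the 4 libraries with intestinal transcripts (log2 −0.38).

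Against Poly(I:C), 471 genes were higher and 104 lower, and against QS-21 626 and 244 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). Past both single treatments lay 412 genes higher and 79 lower, from the larger p of both tests, and the 412 became 259 without the 4 libraries with intestinal transcripts. Adjusted p was 1.26e-15 and 7.35e-18 for Cxcl10 and 1.03e-13 and 9.45e-16 for Ifit1 in the 2 edgeR tests. Of 28 lists 22 passed camera in each comparison, and 17 and 15 with an estimated correlation. In both, the latter held for interferon-stimulated genes (adjusted p = 2.32e-05 and 1.30e-05), MHC class I (0.000649 and 0.000472), NF-kB targets (0.000453 and 0.000472), the stress response (0.000649 and 0.000534) and cell cycle (0.000848 and 0.000494). Cholesterol genes were lower in 3 and 4 of 25 cases (3 and 5 adjusted over the list alone; medians −0.10 and −0.05). Their list passed camera as lower in both (adjusted p = 0.00238 and 0.0117 with an estimated correlation). The 104 lower genes became 44 without Poly(I:C) 2, 69, 63 and 45 without combination 1, 2 and 3, 45 when only the groups compared were fitted, 25 without the 4 libraries with intestinal transcripts and 183 with DESeq2, and the 244 became 144, 149 and 132 without QS-21 1, 2 and 3, and 154 and 130 without combination 1 and 3. The 79 became 28 and 49 without Poly(I:C) 2 and 3, 50, 48 and 51 without QS-21 1, 2 and 3, 40, 45 and 31 without combination 1, 2 and 3, 132 with DESeq2, and 7 without the 4 libraries. Summed counts of the 19 low-count heart genes were 121 to 369 in the single-treatment libraries and 65 to 107 in the combination, Myh6 had at most 3 in the latter, and 4 and 5 of 20 tested heart genes were among the lower calls.

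The interaction contrast asks whether the combined change differs from the sum of both single changes on the log2 scale. Interferon-stimulated genes exceeded that sum in 48 of 53 cases (50 adjusted over the list alone; median 1.95), with Cxcl10 at 3.29, Rsad2, an antiviral radical enzyme, at 3.14, Ifit1 at 3.08 and Isg15 at 2.52. MHC class I genes exceeded it in 17 of 21 cases (19 adjusted over the list alone; median 1.14), including Tapbp at 2.14. NF-kB targets did so in 13 of 19 (15 adjusted over the list alone), with Nfkbie at 2.25. Cholesterol genes fell short of it in 23 of 25 cases (23 adjusted over the list alone; median −1.18), while their median change from either agent alone to the combination was −0.10 and −0.05, with an interaction of −2.26 for Insig1 and −2.11 for Msmo1. Stress response genes exceeded it in 16 of 24 (20 adjusted over the list alone; median 0.39), with Atf3 at 2.29 and Trib3 at 1.92. Cell cycle genes fell short of the sum in 18 of 34 cases and exceeded it in 1 (25 and 1 adjusted over the list alone, median −0.29).

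Of the interaction genes 713 lay above the sum and 516 below (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). Adjusted p in this test was 2.95e-12 for Cxcl10, 2.33e-10 for Ifit1 and 4.80e-13 for Insig1. Of 28 lists 19 passed camera and 16 with an estimated correlation, among them interferon-stimulated genes (adjusted p = 8.62e-05), MHC class I and NF-kB targets (0.0023 each), cholesterol genes (2.68e-06) and the stress response (6.49e-05). The contrast sets vehicle and combination against both single treatments, which is also the split of the libraries by Myh6 counts, and 6 of 20 tested heart genes were among those below the sum. Without the 4 libraries with intestinal transcripts 198 lay below the sum, and with vehicle 3 as the only vehicle library 393 lay above and 211 below.

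The 2 pairs of effects that follow share no library and were set side by side. In each pair the effects cross the split by Myh6 counts in opposite directions, since single-treatment libraries are compared with vehicle in the first effect and serve as the reference for the combination in the second. The QS-21 effect without Poly(I:C) and its effect with Poly(I:C) correlated across 13850 genes at r = 0.067 (Spearman −0.070). Of genes higher after QS-21 alone 37 were also higher when it was added to Poly(I:C), against 19.9 for independent lists, and 49 were lower, against 4.4. Of those lower after QS-21 alone 8 were also lower, against 4.1, and 52 were higher, against 18.4. For the Poly(I:C) effect without and with QS-21 r was 0.322 (Spearman 0.013), with 187 genes higher in both against 30.9, 29 lower in both against 10.9, 66 higher without and lower with QS-21 against 12.1, and 52 the other way against 28. The latter r became 0.024 without the filter on low counts, 0.478 with a minimum of 1 CPM and 0.037 with DESeq2, and it was 0.159 with vehicle 3 as the only vehicle library. The former r was 0.044 without vehicle 1, 0.043 without Poly(I:C) 3, 0.044 without QS-21 3, 0.102 without combination 3, 0.027 without a filter, 0.032 with DESeq2, 0.006 with a minimum of 1 CPM, −0.058 with vehicle 3 as the only vehicle library and 0.003 without the 4 libraries with intestinal transcripts.

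The genes named most often are protein-coding and lie, with positions as the table gives them, at chromosome 5 from 92494497 to 92496748 on the minus strand (Cxcl10, ENSMUSG00000034855), chromosome 19 from 34618271 to 34627409 on the plus strand (Ifit1, ENSMUSG00000034459), chromosome 4 from 156283912 to 156285253 on the minus strand (Isg15, ENSMUSG00000035692), chromosome 5 from 28276361 to 28283660 on the plus strand (Insig1, ENSMUSG00000045294) and chromosome 2 from 119181710 to 119184862 on the plus strand (Chac1, ENSMUSG00000027313). The build is not given in the sources used here.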

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

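The tests of how heart transcripts relate to the groups were all chosen after the result had been seen, and so were the settings that leave out vehicle 1 and 2 or the 4 libraries with intestinal transcripts. The results here were singled out because the QS-21 effect differed with and without Poly(I:C) in a test of the difference itself, the interaction contrast. It held for 713 genes above and 516 below the sum of both single effects and for 19 gene lists, or 16 with an estimated inter-gene correlation. Outlying single libraries were not looked for, since each group has 3.

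Among antiviral and interferon-induced genes the interaction was 3.29 on the log2 scale for Cxcl10, 3.29 for Ifit3b, 3.08 for Ifit1 and 2.52 for Isg15. For the low-count genes it was 4.81 for Slfn2, 3.74 for Iigp1 and 3.32 for Zbp1. The Zbp1 call ended without vehicle 1 (2.80), vehicle 2 (3.35), QS-21 1 (2.98) or combination 3 (3.28). That of Iigp1 ended without vehicle 2 (2.31) or QS-21 1 (3.56), and its sign turned with vehicle 3 as the only vehicle library (−1.73) and without the 4 libraries (−1.33). The Slfn2 call ended in these 2 settings (3.22 and 4.40). Among sterol genes the interaction was −2.33 for Idi1, −2.26 for Insig1, −2.11 for Msmo1 and −1.91 for Fdft1. The cholesterol list stood at medians of 1.15, 1.09 and 1.04 above vehicle after Poly(I:C), QS-21 and both. An offset of the vehicle libraries from all treated groups would by itself give negative interactions of this kind. It cannot be told apart here from a QS-21 effect that differs with Poly(I:C).

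Myh6 counts split the libraries just as the interaction contrast does, single treatments against vehicle and combination. Library depth is argued against as their source: mean totals had a ratio of 0.93, while Myh6 counts were 479 against 9. Traces of heart RNA or of a heart library may be the source, since 94.7% of low-count heart markers were higher in the single-treatment libraries, against at most 60% for another tissue, with Myh6 at up to 146 counts. Whether a handling difference that came with these transcripts also moved melanoma genes cannot be told apart from the interaction, because no group was handled both ways. Of 1229 interaction genes, 569 had both single treatments called the same way against vehicle, with the combination called that way too for 337 and not called for 228, and 379 of the 1229 lay past both single treatments. For the 337, an offset of the vehicle libraries from all treated groups could also give the interaction.

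Other groupings of the libraries were also counted. For each comparison of 2 groups the 10 possible splits are too few for a share under 0.05. By adjusted calls 1 split, the real one, reached the real number of genes, and 1 the real number of lists. The real splits gave 1303, 1125, 1799, 575 and 870 genes for Poly(I:C), QS-21 and the combination against vehicle and the combination against Poly(I:C) and QS-21. The highest other split gave 0 in each (edgeR, adjusted). At an unadjusted p under 0.05 the real splits gave 2941, 2957, 3532, 1932 and 2302 and the highest other 2253, 1605, 1757, 2424 and 1134, so that for the combination against Poly(I:C) another split gave more, with 2317 in a further one. Lists numbered 17, 15, 19, 22 and 22 against 15, 14, 15, 17 and 15. In 100 draws over all 12 libraries, the real grouping among them, only the real one gave as many interaction genes (1229, highest other 944). It alone also gave as many genes past both (491, highest other 0, and 1408 and 688 unadjusted). These counts argue only against no group effect at all, since a draw mixes libraries of different treatments. They do not test the interaction apart from other group effects, nor chance between cultures, since the libraries may be technical. With the preset correlation 7 draws, the real one among them, gave as many interaction lists (19, highest other 21), so chance cannot be excluded for their number. With an estimated one the real grouping gave 16 lists and the highest other draw 7. DESeq2 was not run on the splits.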

How the results depend on the processing

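The settings with vehicle 3 alone and without the 4 libraries with intestinal transcripts (vehicle 1 and 2, Poly(I:C) 2 and 3) were chosen after the data had been seen; all others were planned. Both leave fewer libraries, and with 1 library left in a group that library is taken to vary like the others. For genes named by rule, 10413 of 10959 tests under an alternative kept the call or its absence. Of the others 444 lost and 100 gained a call, and 2 turned. For lists 3147 of 3326 kept it, 128 lost and 46 gained a call, and 5 turned. A change of sign was counted as turned only where either fit gave a call. RLE factors kept each count within 1.5 times. The causes of the shifts below were not tested beyond what fewer libraries or genes imply.

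With an estimated correlation 9 lists passed for QS-21. Agreement of the Poly(I:C) effect with and without QS-21 (r = 0.322) was 0.024 without a filter, 0.478 with a minimum of 1 CPM and 0.037 with DESeq2, and that of the QS-21 effect (0.067) was 0.006 with 1 CPM. Genes lower in the combination than after Poly(I:C) (104) numbered 45 in a fit of those groups only and 183 with DESeq2, which also gave 132 lower than both (79).

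With vehicle 3 alone, higher and lower genes were 218 and 197 for Poly(I:C), 103 and 137 for QS-21, 465 and 256 for the combination and 393 and 211 for the interaction, and agreement was −0.058 for QS-21 and 0.159 for Poly(I:C). Without the 4 libraries they were 226 and 264, 130 and 175, and 498 and 267 against vehicle, 25 lower than Poly(I:C), 198 below additive, and 259 higher and 7 lower than both, with agreement of 0.003 and 0.15. Values that turned were the Iigp1 interaction (−1.73 and −1.33 in these settings) and ribosomal protein medians: 0.04 for QS-21 in both, and 0.22 for Poly(I:C) and −0.21 for the interaction without the 4 libraries. The ribosomal median of the combination against Poly(I:C) ran from −0.08 without combination 1 to 0.07 without Poly(I:C) 1.

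Leaving out 1 library gave 454 to 743 higher and 377 to 625 lower genes for Poly(I:C), 322 to 657 and 315 to 637 for QS-21, 44 to 115 lower than Poly(I:C), 130 to 305 lower than QS-21 and 28 to 76 lower than both, and agreement of the Poly(I:C) effect of 0.247 to 0.298. The planned change of pseudocount was not run because counts were given. Depth limits genes such as Ifnb1, with at most 4 counts.

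The replicate numbers were not taken to pair the libraries, since not every same-numbered pair deviated together: 6 of 18 same-numbered pairs had deviations correlated above 0.1 (range −0.201 to 0.31), and 7 of 12 libraries were closest to their own number. Number 1 of vehicle, Poly(I:C) and combination (0.248, 0.26 and 0.31) and number 3 of vehicle, Poly(I:C) and QS-21 (0.182, 0.125 and 0.184) did, so a batch shared by some libraries is not excluded. With the number as a replicate block, higher and lower genes were 872 and 813 for Poly(I:C), 790 and 717 for QS-21, 1298 and 955 for the combination, 565 and 152 against Poly(I:C), 699 and 341 against QS-21, 897 and 691 for the interaction and 491 and 109 past both.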

Other observations

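Of the tests below, those of cholesterol genes with vehicle 3 alone, against handling and against the vehicle cultures, those of interferon-stimulated genes against the sum of effects and against handling, and the KEGG enrichment were chosen only after the result had been seen.

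Of 13 immune checkpoint ligands 4 were higher in the combination than in vehicle (5 adjusted over the list alone; camera, adjusted p = 0.00816 with an estimated correlation): Cd274 2.52-fold, the galectin Lgals9 2.40-fold, from 92.4 ± 1.8 to 222 ± 2.3 CPM, and Cd47, a signal against phagocytosis, 1.59-fold. Tlr3, the endosomal receptor for double-stranded RNA, rose 4.15-fold, and 7 of 21 genes of its sensing list were higher (7 adjusted over the list alone; 0.0457 with an estimated correlation). Mlkl, the membrane effector of necroptosis, rose from 57.2 ± 0.38 to 113 ± 4.4 CPM, with 3 of 8 list members higher (4 adjusted over the list alone; 0.0486). Casp4, which senses cytosolic lipopolysaccharide, rose 5.88-fold, but its inflammasome list was lost with an estimated correlation (adjusted p = 0.139).

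Some genes of the glycolysis and hypoxia list were higher after the single treatments. Bnip3, a mitophagy receptor, was at 1.82-fold after Poly(I:C) and 1.52-fold after QS-21, and Pdk1, which keeps pyruvate from the mitochondria, at 1.49-fold and 1.52-fold, the former call of Pdk1 ending without the 4 libraries with intestinal transcripts (log2 0.39). Their list had 6 and 7 of 25 genes higher and 1 lower in each (9 and 7, and 1 in each, adjusted over the list alone; medians 0.07 and 0.09; camera, adjusted p = 0.0288 and 0.0102 with an estimated correlation). In the combination 6 were higher and 1 lower than in vehicle (7 and 1 adjusted over the list alone; median 0.09; adjusted p = 0.206 with an estimated correlation). In the test of the difference, the interaction, 5 were below the sum (6 adjusted over the list alone; median −0.15; adjusted p = 0.00391 with an estimated correlation), a contrast that follows the split by Myh6 counts. The list was also lower in the combination than after Poly(I:C) and QS-21, in 2 and 4 genes (3 and 4 adjusted over the list alone; medians −0.04 and −0.07; adjusted p = 0.0345 and 0.0157 with an estimated correlation), and both comparisons cross that split. Gapdh of this list stood at 77.9, 603 and 83.7 CPM in the 3 vehicle libraries. Among KEGG terms, steroid biosynthesis had 13 of 16 genes higher after each agent (adjusted p = 3.84e-11 for Poly(I:C) and 9.07e-12 for QS-21, hypergeometric), and genes higher in the combination than in both singles were enriched for Epstein-Barr virus infection (44 of 146, adjusted p = 7.9e-25).

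Cholesterol genes stood higher in all 3 treated groups than in vehicle. Low-count background in vehicle 1 and 2 is argued against by a smallest median of 1.0 with vehicle 3 alone. The choice of TMM factors is argued against by 1.04 with RLE factors, but a scaling error common to both was not tested. For the combination against vehicle, both with few Myh6 counts, the handling marked by heart transcripts is argued against by a median of 1.04. The medians of 1.15 after Poly(I:C) and 1.09 after QS-21 come from comparisons that cross the split, so handling cannot be told apart there. A difference in the vehicle cultures themselves may account for the pattern: the treated groups differed by at most 0.1 in median, which treatments with a like effect would also give. The list was still lower in the combination than after Poly(I:C) and QS-21 (camera, adjusted p = 0.00238 and 0.0117 with an estimated correlation). Both of these comparisons cross the split by Myh6 counts. A difference in the vehicle cultures cannot be told apart from an effect of the treatments, which stays untested, because every treated group was set against the same 3 vehicle libraries.

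Interferon-stimulated genes lay past both single treatments in the combination. The choice of TMM factors is argued against as the source by a smaller median of 2.05 with RLE factors. A scaling error common to both kinds of factor was not tested. The sum of both effects is argued against by a QS-21 median of 0.04, beside 2.05 for the combination against Poly(I:C), and by 48 of 53 members past the interaction test. That median of 0.04 also argues against a like handling shift of these genes in all single-treatment libraries without a QS-21 effect. QS-21 against vehicle crosses the same split and would then lie at −1 or lower. It holds no Poly(I:C), so it cannot decide on handling that changed only the response to Poly(I:C). Handling offset by a QS-21 rise of like size cannot be told apart, since no libraries of like handling hold both the combination and Poly(I:C); combination against vehicle, which lacks that split, had a median of 3.85.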
